A study of Glycine max with 8 samples.

How the data were processed

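Total RNA of whole black soybean sprouts, about 0.5 cm or 5 cm long, was labelled with Cy3 and hybridised to 1-colour Agilent soybean oligonucleotide arrays, 1 sample per array, per the labels. The 8 arrays lay on 2 slides, and each slide held 2 arrays of each length. All arrays of a slide shared a scan, so slide and scan form 1 batch. Groups and replicate numbers came from the sample titles.

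The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction version 10.7.3.1 per the submitters' processing notes. Per the file headers these are processed signals with the background subtracted within each array and no scaling between arrays. A deposited table of the authors' scaled intensity for the whole series is also linear. Each of its columns equals the processed signal of the array times 1 constant (from 0.767 to 1.81 over the arrays), rounded to whole numbers, so that all columns share a mean of 2592. Its medians were 258, 254, 232.5 and 221 for replicates 1 to 4 of the 0.5 cm sprouts and 344.5, 373, 345 and 339 for those of the 5 cm sprouts. It is not centred by probe. The tool that scaled it is not given in the sources used here.

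Of 44165 spots per array, 1417 control spots were left out, which leaves 42748 soybean probes with 1 spot each. The analysis used log2 of the processed signal minus the array's 75th percentile over these probes. Spots flagged as non-uniform or population outliers (196 over all arrays) were treated as missing. There were 0 saturated soybean spots and 0 values at or under 0. Many dim spots of an array shared 1 low value, however. The median over the spots of control probes DarkCorner and RC1 was 1.52 for both on 0.5 cm replicate 1. On 5 cm replicate 1 it was 2.33 for both (log2, before scaling). Many soybean probes well above background only in 5 cm sprouts likewise had 1 identical mean in 0.5 cm sprouts. The fitted difference, spread and p-value of such probes rest on that shared value. A probe was tested if it was well above background on at least 3 of the 4 arrays of at least 1 group, which left 36351 probes and put 6397 aside. The precision is limited by the number of arrays.

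Differences (5 cm minus 0.5 cm) were fitted with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3 with the data.table package (version 1.17.8). P-values were adjusted by the Benjamini-Hochberg method over all tested probes, with a two-sided threshold of 0.05. Single measures of the arrays were compared by exact permutation tests over all 70 assignments of the arrays, which ignore the slides; within slides there are 36 assignments and the smallest p is 0.0556. For a probe not well above background in one whole group, the change is given as a bound. The bound is the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal called well above background and the probe's own signal. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3.

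The design, tests and most alternatives were fixed before the data were examined. The named-gene rule asked for the largest rises and falls among probes with a product name, and for members of fixed gene lists. The deposited files hold no product names or gene symbols, and 0 probe accessions matched the reference table of the Glycine_max_v4.0 assembly (59048 genes). The gene lists, their set tests and the named genes could therefore not be used. In their place, 2 probes that rose and 2 that fell were taken by the same rule without the product name.

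The fit was tested on simulated data for this comparison, with 36351 probes, 4 arrays per group and the real probes' spread, of which 200 were changed. It recovered 8% of the 50 probes changed 1.5-fold, 38% of those changed 2-fold, 84% at 4-fold and 86% at 8-fold, all 108 with the right sign. It made 4 calls among unchanged probes, and 0 calls in data simulated without any change. With so few changed probes the adjustment is stricter than in the real data.

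Alternatives covered the scaling (quantile, medians), the background correction (normexp with offset 50), the filter on dim probes, slide and replicate number as blocks, each slide alone, the authors' scaled table, the variance model, array weights, outlier spots, and leaving out each array. The files hold no mean foreground signal, so normexp was run on the median signal.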

Results

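RNA was measured in whole sprouts of a black soybean (Glycine max) variety, germinated in darkness and collected at a length of about 0.5 cm or about 5 cm. The series' design text describes 4 independent experiments with different sprouts in each group, so each group holds 4 arrays with 1 sample each. The comparison asks which transcripts differ in level between the short and the long sprouts. Each array carried 42748 soybean probes with 1 spot each. The files pair no probe with a gene: each probe carries a sequence accession, and 0 of the 42748 matched the reference gene table. The results therefore describe probes, by their identifiers and in groups set by detection and brightness, and no gene is named.

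More probes were well above background on the arrays of 5 cm sprouts, and a technical cause stays open. On average 35672 ± 672 probes (SD, n = 4) were well above background in 5 cm sprouts, against 33285 ± 400 (SD, n = 4) in 0.5 cm sprouts. That is 83.4% against 77.9% of the soybean probes. The counts ran from 34697 to 36224 in the 5 cm group and from 32718 to 33610 in the 0.5 cm group, so the groups did not overlap. The difference of 2387 probes had a two-sided exact permutation p of 0.0286, the smallest that 4 arrays against 4 can give. Permuting only within slides gave an exact p of 0.0556, the smallest that its 36 assignments allow, so this permutation cannot pass 0.05. Within slide 1 the difference was 2454 probes and within slide 2 it was 2320. The 5 cm arrays were also brighter: the 75th percentile of the processed signal averaged 1928 ± 175 against 1263 ± 384 units (SD, n = 4 each), with an exact permutation p of 0.0286. Under the less strict flag for signal above background, the difference was 949 probes and its exact permutation p was 0.0571. Without replicate 1 of the 0.5 cm sprouts the difference was 2198 probes, also with an exact permutation p of 0.0571.

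**Figure D1:**
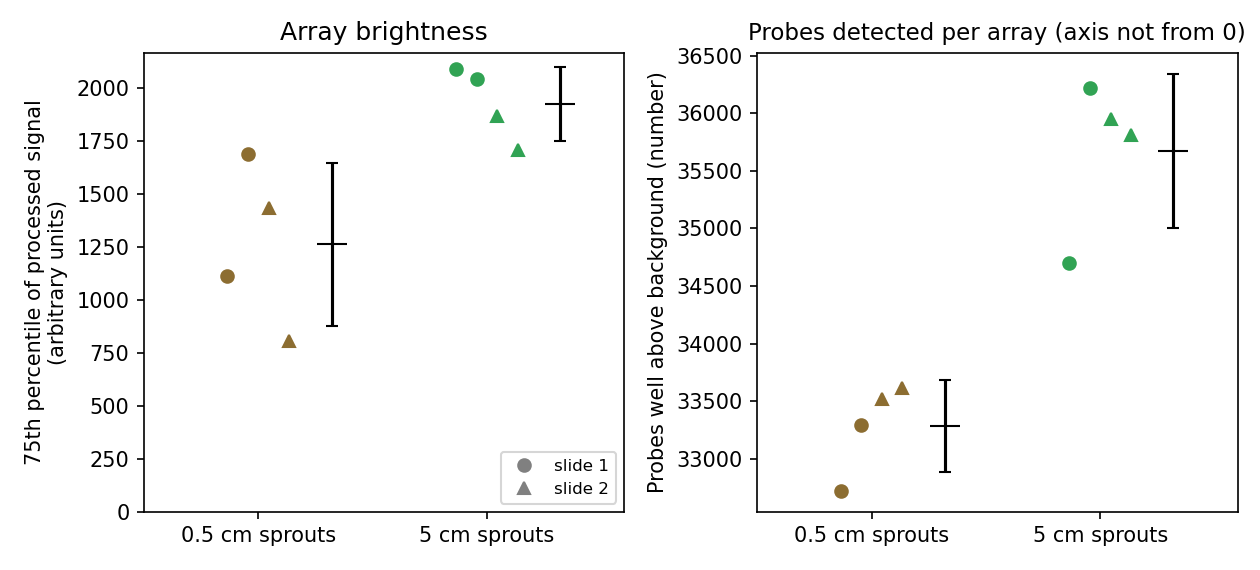
The left panel shows the 75th percentile of the processed signal in arbitrary units and the right panel the number of probes well above background, for each array of 0.5 cm and 5 cm sprouts. Each point is 1 array (circles slide 1, triangles slide 2) and the bars give the mean and SD of 4 arrays; on both measures every 5 cm array lies above every 0.5 cm array, with 34697 or more probes detected against 33610 or fewer.

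Detection that was complete in one group and missing in the other was mostly on the side of the long sprouts. In all, 2027 probes were well above background on all 4 arrays of 5 cm sprouts and on no array of 0.5 cm sprouts. The opposite pattern was found for 401 probes. The flag was set within each array, the 5 cm arrays were brighter, and array position cannot be separated from sprout length. A technical cause of this imbalance therefore stays open, and these counts were not repeated at a common floor. All 2027 and 400 of the 401 passed the test of the difference, which their choice by detection on the same arrays largely fixed. Many of the 2027 held the shared low value on the 0.5 cm arrays, so their spread there was not measured. Under the less strict flag for signal above background these counts were 603 and 138. A probe of this kind has only a bound on its change. The bound sets the mean of the bright group against the dimmest signal called well above background on each array of the dim group, or the probe's own signal where that was higher. Among the 2026 probes detected only in 5 cm sprouts with a bound above 1, the median was at least 8.56-fold higher, and 718 probes were at least 16-fold higher. Among the 400 such probes detected only in 0.5 cm sprouts, the median was at least 4.11-fold lower in the long sprouts, and 86 were at least 16-fold lower. The largest bounds were at least 2684-fold higher and at least 1147-fold lower. All these bounds are relative to each array's 75th percentile and hold on that scale only. With the median of all soybean probes as the scale, log2 differences moved by -0.52. Bounds on rises would then be smaller and bounds on falls larger, so the gap between the 2 median bounds depends on the scale. The medians and counts of these bounds were not repeated on other scales. A further 30038 probes were well above background on all 8 arrays, and 4111 were so on none.

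Most of the tested probes differed in signal between the lengths. Of 36351 probes tested, 28133 (77.4%) differed between 5 cm and 0.5 cm sprouts at an adjusted p below the threshold of 0.05. Among these, 14213 were higher and 13920 lower in 5 cm sprouts relative to each array's 75th percentile. A difference of at least 2-fold was found for 19519 probes, 10802 higher and 8717 lower. With the 2292 higher and 528 lower probes that were not well above background on any array of one group set at their bound, 18923 probes differed by at least 2-fold, 10372 higher and 8551 lower. The balance at 2-fold depends on the common scale: as fitted it was 9179 higher and 11538 lower under quantile scaling, 9239 and 11637 relative to the median of the tested probes, and 8489 and 13453 relative to the median of all soybean probes. With bounds, 2310 probes were at least 16-fold higher and 492 at least 16-fold lower. The corresponding counts were 1812 and 670 under quantile scaling, 1950 and 610 with the tested-probe median, and 1792 and 698 with the all-probe median. The median rise over the 14213 higher probes was 1.94 on the log2 scale as fitted and 1.74 with the bounds. The median change of the 13920 lower probes was -1.23 as fitted and -1.20 with the bounds. Among probes well above background on all 8 arrays, the median was 1.49 for 10307 higher probes and -1.18 for 12560 lower probes. For 73.1% of the tested probes the values of the groups did not overlap, where chance gives 2.86%. With a normexp background correction of the median signal the count of differing probes was 17524, and it was 26993 when 45 spots of 5 cm replicate 3 with a high local background were left out of the fitted background.

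**Figure D2:**
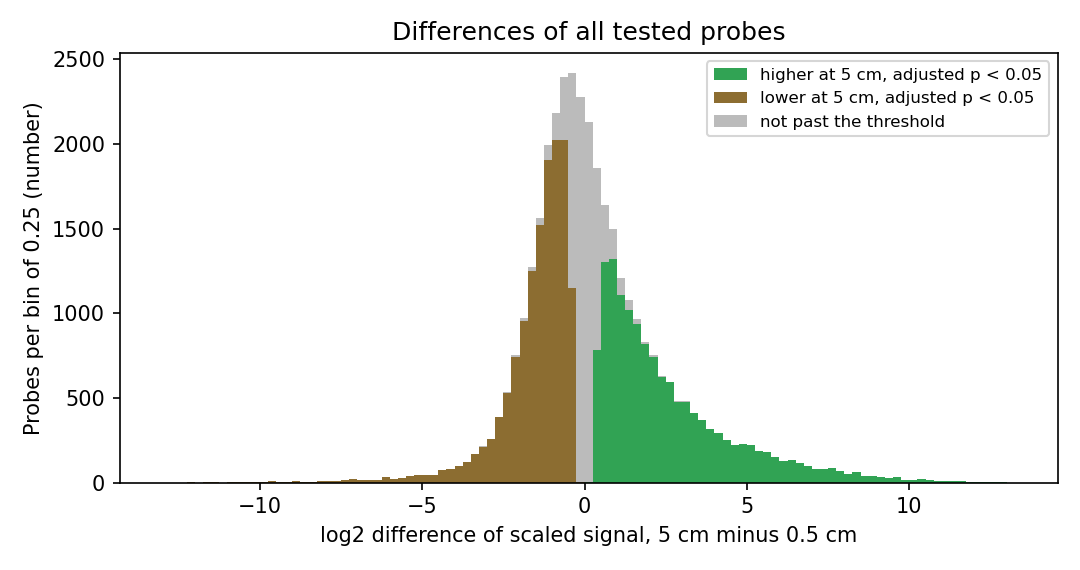
The plot counts the tested probes by their log2 difference in scaled signal, 5 cm minus 0.5 cm sprouts, in bins of 0.25, with probes near the background at their fitted value. Colours separate the 14213 higher and 13920 lower probes from the 8218 that did not pass; on the 75th percentile scale the tail of rises is longer, with 2916 probes higher and 573 lower by a fitted 16-fold or more.

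The balance of higher and lower probes changed with brightness. In the dimmest of 4 equal classes of the tested probes, by mean signal over all arrays, 6754 of 9088 differed and 65.0% of these were higher in 5 cm sprouts relative to the 75th percentile. The share fell through the brightness classes, to 55.8%, 44.7% and, in the brightest class, 37.4% of 7135 probes. Part of this trend is built in, because a probe detected in 1 group only has a low mean signal and more such probes (2027 against 401) were on the side of the 5 cm sprouts. Under quantile scaling, which gives every array the same distribution, the shares from the dimmest to the brightest class were 46.4%, 42.0%, 40.2% and 40.7%. They were 57.4%, 47.3%, 35.1% and 27.2% relative to the median of the tested probes, and 53.4%, 43.1%, 30.6% and 22.2% relative to the median of all soybean probes. Relative to each array's median over all soybean probes, 10864 probes were higher and 18525 lower, because that median lay 0.52 closer to the 75th percentile on the log2 scale in 5 cm sprouts (-2.19 ± 0.03 against -2.71 ± 0.07, SD, n = 4 each).

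The largest changes measured on both sides depended in size on the background treatment. They are given for the largest 2 rises and 2 falls among 21439 probes that differed, were well above background and unsaturated on all 8 arrays, and had groups that did not overlap. Without gene names, these probes could not be chosen by the full rule set in advance. They were chosen by size, call and lack of overlap on the same arrays, so their adjusted p-values and spreads add no separate support. The scaled log2 signal of probe GMFL01-52-F01-R_375 was -5.85 ± 0.48 in 0.5 cm and 5.91 ± 0.08 in 5 cm sprouts (SD, n = 4 each), a rise of 11.76 ± 0.22 (SE, limma adjusted p = 4.99e-09), which is 3465-fold here and 617-fold to 852-fold under the 3 normexp settings. Probe GMFL01-14-E16-R_712 rose from -5.91 ± 0.50 to 5.70 ± 0.47 (SD, n = 4 each), by 11.60 ± 0.30 (SE, limma adjusted p = 1.47e-08). Probe BI973760.1_373 fell by 11.55 ± 0.13 (SE, limma adjusted p = 2.11e-09), with means of 5.29 ± 0.19 and -6.26 ± 0.12 (SD, n = 4 each), which is 3001-fold lower here and 453-fold to 815-fold lower under normexp. Probe BU545462.1_492 fell by 11.44 ± 0.27 (SE, limma adjusted p = 9.50e-09), with means of 6.55 ± 0.09 and -4.89 ± 0.60 (SD, n = 4 each). The SE does not cover the choice of background treatment. Under normexp, whose added offset compresses differences of dim signals, the second rise was 9.12 to 9.53 and the second fall -9.58 to -10.34 on the log2 scale. All 4 kept their direction and their call under every scaling and on each slide.

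**Figure D3:**
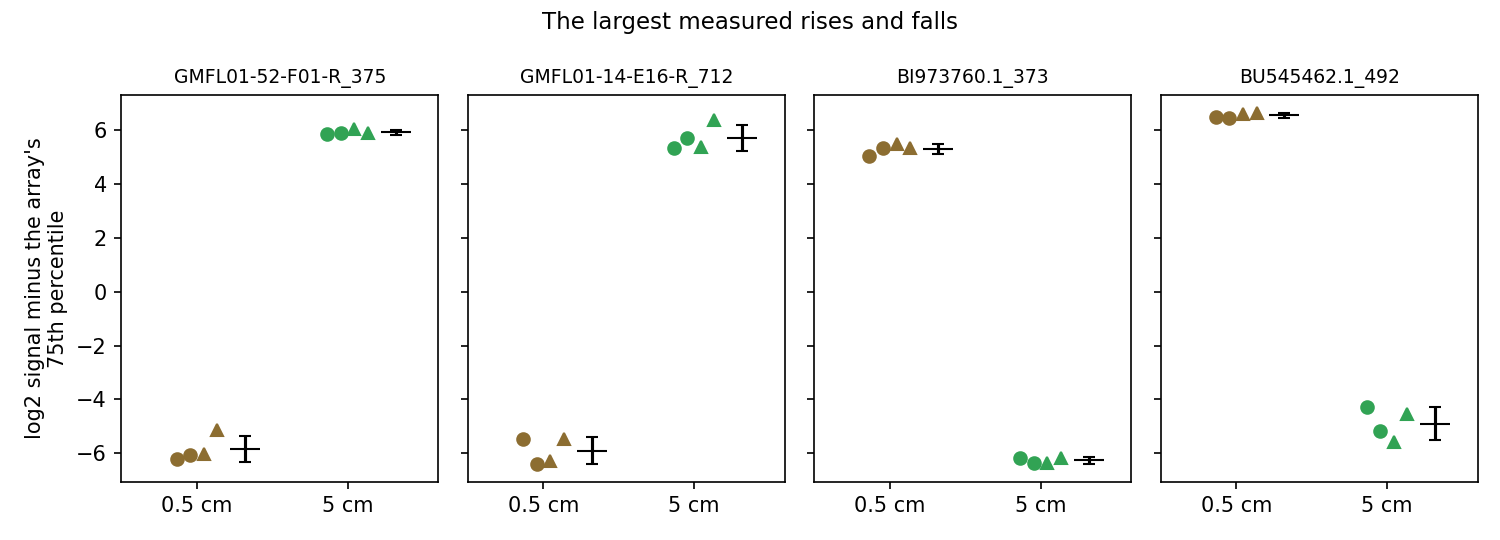
Each panel shows the log2 signal of 1 probe minus the array's 75th percentile, for the arrays of 0.5 cm and 5 cm sprouts. Points are single arrays (circles slide 1, triangles slide 2) and bars the mean and SD of 4 arrays; the left pair of probes rose by 11.76 and 11.60 and the right pair fell by 11.55 and 11.44 on the log2 scale.

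The arrays of a group resembled each other far more than those of the other group. Across tested probes, the correlation between arrays ran from 0.965 to 0.989 within groups and from 0.678 to 0.714 between groups; probes are not independent replicates. The median SD of a probe was 0.27 on the log2 scale in 0.5 cm and 0.19 in 5 cm sprouts. Both slides held 2 arrays of each group. Of 27638 probes that differed and had a value on both slides, 27637 had the same sign on each slide and overall. Their choice by the test over both slides largely fixed this agreement. With the slide as a block, 28862 probes differed between the lengths, and within slide 1 and slide 2 alone 25695 and 22916 did. In the fit with sprout length and slide together, 573 probes differed between the slides. The position on the slide cannot be separated from sprout length, because 0 of the 5 cm arrays lay at position 1 or 2.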

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

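All explanations of detection and control spots below were tested after the result was seen; the splits of the arrays were planned. Chance flags about 1 in 20 groups of array values, and 2 of 26 groups examined had an array standing apart.

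The positive control probe (+)eQC-40, which no comparison uses, has 10 spots per array. Control values here and below are each array's median log2 signal over a probe's spots, averaged over the arrays of a group. For eQC-40 this was 15.82 ± 0.09 on the 5 cm arrays and 4.59 ± 0.26 on the 0.5 cm arrays (SD, n = 4 each). On the 0.5 cm arrays 38 of 40 spots were still called well above background. The difference was 11.23, with an exact permutation p of 0.0286. Bright artefacts on single spots are argued against, since 40 of 40 spots over the 5 cm arrays were well above background and none lay more than 0.33 on the log2 scale from its array's median. A mix of external control RNAs added to the 5 cm samples is argued against as well, because none of 13 other external control probes (E1A and eQC) had a mean log2 signal above 4.45 on the 5 cm arrays, or above 4.39 on the 0.5 cm arrays. A sprout transcript that binds the probe and a single added RNA both stay open, since the probe's target is not given. Among soybean probes, 28 rose by at least as much as its scaled signal did (10.57 on the log2 scale). Probes not well above background on any 0.5 cm array were taken at their bound, and the other rising probes at their fitted value. A rise of this size thus occurred among soybean probes, which does not show that a transcript binds this probe.

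More probes were well above background in 5 cm sprouts, where the arrays were also brighter. If the 0.5 cm arrays were dimmer by 1 common factor per array, scaling and a common floor would remove the difference. At that floor the 5 cm arrays still held 2294 more probes on average, and the larger of the ranges within a group was 1108, which argues against such a factor as the whole cause. It does not bear on a loss that was greater for dim probes than for bright ones, which stays open: after scaling the median probe was still lower on the 0.5 cm arrays (-2.71 against -2.19). Array position on the slide cannot be told apart from sprout length, since 0 of the 5 cm arrays lay at position 1 or 2, and a wider set of active genes in the larger sprouts could also give this pattern and was not tested.

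In 5 cm replicate 1, 38631 probes carried the less strict flag for signal above background, apart from 39539 to 39725 in the other arrays of its group. In 0.5 cm replicate 1, 108 spots were flagged as outliers, against 0 to 5 in the other arrays of its group.

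The counts of differing probes were far larger in the real split of the arrays than in any other. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many probes that differ (28133), as many in one direction (14213 higher, 13920 lower) or as many that differ at least 2-fold (19519). The highest count in another split was 35 probes for each of these, in the split that follows the slides, fitted without sprout length. Each other split mixed the lengths, so the length difference entered its residual spread and lowered its count. The smallest share that the splits can give is 1 of 35, and they do not bear on array position.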

How the results depend on the processing

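The normexp, common-floor, all-probe-median, 16-fold and less strict detection settings were chosen after seeing the data. Planned normexp runs on the mean signal could not be made because the files hold none, and the set tests (camera with an estimated correlation, probe means, fry) were not run because no probe has a gene name. The count of differing probes (28133) stayed within 1.5 times under all alternatives but one, as did the counts in each direction and, with the directions together, at 2-fold. Under normexp on the median signal it was 17524, with 7586 lower probes and 12807 at least 2-fold. There, 45 spots of 5 cm replicate 3 with a local background above 100 (up to 192117, against at most 48.5 on the other arrays) set off that array's fitted background. With those spots left out of the fit, 26993 probes differed. The 2-fold counts by direction (10802 higher, 8717 lower) moved further. They were 7950 and 4857 under normexp, and 6764 and 7335 under normexp with quantile scaling. With those spots left out they were 7593 and 7321, and relative to the median of all soybean probes 8489 and 13453. Leaving out each array in turn gave 26709 to 28306 differing probes. Quantile scaling moved the median log2 difference by -0.29, the median of tested probes by -0.33 and the median of all soybean probes by -0.52. The calls were then 12225 higher and 16677 lower, 12000 and 16942, and 10864 and 18525. Under quantile scaling 25688 of the 28133 probes were called again, 62 of them with the other sign and 0 of these at least 2-fold.

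With the replicate block, 28254 probes differed. The labels give same-numbered arrays of the lengths no shared batch, though each such pair lay on 1 slide. Their deviations correlated at 0.18, 0.32, -0.03 and 0.12, so not every pair deviated together, and 4 of the 8 arrays correlated best with their own number.

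The difference of 2387 probes well above background lost its call under the less strict flag (949, exact permutation p of 0.0571) and without 0.5 cm replicate 1 (2198, exact permutation p of 0.0571), and was 2198 to 2711 over the arrays left out. Without 0.5 cm replicate 1 the groups were unequal in size but still did not overlap (33296 to 33610 against 34697 to 36224). Under the less strict flag, 603 probes were detected only in 5 cm and 138 only in 0.5 cm sprouts. Within slide 1 and slide 2, with fewer arrays required, 674 and 711 were detected only in 0.5 cm sprouts. The 4 named probes kept their direction and call in every setting, but were smaller under the 3 normexp settings, for example -8.82 to -9.67 against -11.55 for BI973760.1_373. Signal near the background limits the dimmest probes.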

Other observations

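The tests here were chosen after differences between accession groups had been seen, and the test by brightness was set before its result.

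The share of rising probes differed between groups of probes set by the letters that open a probe's accession, here called collections. The letters alone do not show that such a group had a single source. Over the 14 collections with at least 500 tested probes (27548 differing probes), the share higher in 5 cm sprouts ran from 36.5% in BM (1635 probes) to 68.4% in CD (1138 probes). The BW collection, the largest with 6969 differing probes, had 57.4%. The 95% Wilson intervals were 34.2% to 38.9% for BM and 65.6% to 71.0% for CD, and cover counting error only, since probes are not independent. Shuffling directions over probes gave a permutation p of 1e-05, the smallest that 100000 permutations can give. The shuffle also treats probes as independent, so this p makes no allowance for probes that move together. Within slide 1 the shares were 36.3% and 68.1%, and within slide 2 they were 36.5% and 68.3%. These are shares of the probes called over both slides, so their choice largely fixed this agreement and it adds no separate support. Quantile scaling lowered both, to 25.6% and 62.6%, and kept their order.

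Differences in probe brightness are argued against as the whole cause of the gap between CD and BM. In each of the 4 brightness classes the CD share lay above the BM share, by 22.8 to 39.5 percentage points. CD and BM were picked as the highest and lowest collections on these same probes, which favours a gap in this direction. The other collections were not compared by class. A hypothesis that may account for the rest is that the collections were drawn from different tissues or stages, so that some hold more transcripts of grown seedlings and others more of young ones. The files do not say what each collection was made from, or whether it had a single source. The hypothesis was therefore not tested. Several probes of 1 gene within a collection could also widen or narrow the gap, which was not tested either.

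The bright corner spots, well above background on all 8 arrays, were higher by 1.10 on the log2 scale on the 5 cm arrays before scaling, with an exact permutation p of 0.0286 (n = 4 each, not adjusted for the number of control probes). Probe (+)E1A_r60_a22, with 122 of 128 spots well above background on the 0.5 cm arrays and 75 of 128 on the 5 cm arrays, fell by 0.30 before scaling, with the same p. Differences of DCP_20_3, (+)eQC-39 and ETG05_66023 are not given as sizes, because most of their spots were not well above background on the 0.5 cm arrays (1 of 8, 1 of 40 and 1 of 40 were). On the 5 cm arrays 3 of 8, 0 of 40 and 24 of 40 were. The control probe ETG10_236652 was bright on all 8 arrays, at 12.38 ± 0.76 in 0.5 cm and 11.73 ± 0.31 in 5 cm sprouts (SD, n = 4 each), a difference that did not pass before scaling (exact permutation p of 0.2). The 75th percentile was higher on the 5 cm arrays (1928 against 1263 units). Relative to it both falls would be larger and the rise of the bright corner smaller, and these calls were not tested on that scale.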
